A study of Homo sapiens with 720 samples.

How the data were processed

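The series holds 720 sequencing libraries of HEK293T cells, a human embryonic kidney line, that carry a fusion of catalytically dead Cas9 with the repressor domains KRAB and MeCP2. Such a fusion is used to silence a gene at the site to which a single guide RNA directs it. Per the labels' protocols, wells of 96-well plates received 12000 cells, guides were delivered 24 h later with a lipid reagent, the wells were lysed 72 h after delivery, and 3'-end sequencing libraries were made from the lysates. For each label, set and number there is 1 library marked as capture data and 1 marked as made without capture (360 of each), where capture is a step that enriches chosen transcripts. The list of transcripts chosen for enrichment was not used here.

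Each library was assigned to its label from its title. There were 34 labels and 6 sets of wells with 60 capture libraries each. Mock, NC1, NC2, NEAT1, DPH1, PROPRO1, PROPRO2, ANTIPRO1, ANTIPRO2 and ANTIPRO3 occurred in every set (12 capture libraries per label). Each of the other 24 labels, most of them named after a long non-coding RNA or its locus, occurred in 1 set with 10 libraries, numbered as 10 guides. NC1 and NC2 served as the reference, NC in what follows. In set 2 some library names carry the suffix bis, whose meaning the labels do not give. There NC, Mock, NEAT1, DPH1 and ANTIPRO3 libraries carry it, ANTIPRO1 and ANTIPRO2 libraries do not, and CTC, FAM215B and LINC00909 guides are mixed. In that set a difference from NC can therefore also reflect whatever the suffix marks. The treatment label of the Mock libraries reads like that of all others and does not say what Mock wells received. The labels do not give what NC, PROPRO and ANTIPRO stand for, and they do not say whether wells came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. For the 24 labels of 1 set the libraries of a label are different guides, so their spread also holds differences between guides.

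The deposited values are counts of reads per gene, given for each library over 58302 genes. Per the submitters' processing notes, reads were checked with FastQC 0.11.8, aligned to hg38 with STAR 2.6.0c and counted with HTSeq 0.11.0. The gene annotation is not given in the sources used here, and 58039 of the gene identifiers (99.5%) were found in GENCODE v29, which supplied gene types and hg38 positions. Gene symbols came from a table of current names matched on the identifier. The capture tables are named as stranded counts. Whether strand was used in counting was not tested. Of the 50 genes with most counts, 21 overlap an annotated gene on the opposite strand. In 19 of these the counts on the opposite strand were under 1% of the gene's own, and the exceptions were EIF3G and P2RY11. Overlapping genes, and ribosomal protein genes with near-identical pseudogene copies, remain uncertain, since reads could be split between them.

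In all 360 no-capture libraries every gene count was 0. Comparisons planned for them, and those of capture with no-capture libraries, could not be computed, including the genes enriched by capture, the capture share, the difference of folds between both kinds of library and the thinning to no-capture depth. The same comparisons were run on the capture libraries instead, which was decided after the no-capture counts proved to be 0.

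A capture library held a median of 306094 counts in genes (807 to 1007209). Reads without a feature, with a median of 94198 per capture library, stayed out of library sizes and tests, as did ambiguous and multiply aligned reads. Of reads in genes or without a feature, a median of 71.5% lay in genes. 6 capture libraries had under 50000 gene counts, none of them of a label present in every set. These libraries carry no molecular identifiers in the tables, so intervals and floors given here cover counting error only. Where a group had 0 counts of a gene, the difference is given as a lower bound against a floor of 3 counts over the group. For 1 to 3 counts the ratio of pooled, depth-scaled counts is given with its exact 95% interval. No pair of libraries of one label and set had identical counts, and in the 1140 such pairs the lowest chi-square per degree of freedom was 1.79, over genes with at least 20 counts in the pair.

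Tests used the edgeR 4.0.16 quasi-likelihood F test (glmQLFit and glmQLFTest) on the deposited counts, with TMM scaling, the filterByExpr filter (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment at 0.05. The labels of every set were fitted together (120 libraries, 1140 genes, label and set as terms), with 12 libraries against the 24 NC libraries. Each of the 24 other labels was fitted within its set of 60 libraries, with 10 guides against 4 NC libraries, and adjusted over all 57128 tests together. The standard error of a log2 fold change is its size divided by the square root of F. Values per library are CPM, computed here from the deposited counts. For label genes, genes of the labels of every set and called genes of single-set labels, the library size was scaled by the TMM factor. For the summed interferon list, and for CPM over all capture libraries together, gene counts alone were the library size. Log2 CPM used a prior count of 2.

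The gene a label names was matched by a rule on symbols, and these label genes were adjusted over their own list of 21 pairs of label and gene. Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated one, where at least 3 members were measured. They cover interferon response, integrated stress and unfolded protein response, the G2/M and S phases, hypoxia and glycolysis, paraspeckles, diphthamide and elongation, ribosomal proteins and mitochondrially encoded genes. Lists of p53 targets (1 measured member), heat shock (2), cholesterol synthesis (2), immediate early genes (2), NF-kB targets (1) and neural progenitors (2) were too small to test, and 4 lists of other cell types (epithelium, fibroblasts, blood, hepatocytes) had 0 measured members. The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. For the labels of every set, the single-set labels and the gene lists, that plan named no-capture libraries. Running them on capture libraries was chosen after the counts were seen. The rule took, for each label of every set, up to 10 called genes with the largest rise and 10 with the largest fall among those with a mean of at least 10 CPM in either group, plus called list members. For the other 24 labels it took the label gene and up to 3 called genes with the smallest adjusted p.

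The procedures were tested on simulated data with 200 changed genes drawn from the real means and library sizes. For Mock against NC (1081 simulated genes passed the filter), edgeR recovered 29.4% of genes changed by a log2 fold of 1, 62.1% at 2 and 92.4% at 4, with 0 of 940 unchanged genes called. Genes that failed the filter count as not recovered or not called. For ZNF6 guides against NC (2129 passed) it recovered 4.41%, 4.55% and 42.4%, with 4 of 2164 unchanged genes called. For ZNF6 guides against the other guides of the set it recovered 13.2%, 39.4% and 87.9%, with 10 called falsely. Both ZNF6 runs adjusted p within that label alone. The single-set calls were adjusted over all labels together, so these rates are not those of that procedure.

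Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, no set term, a block for set and replicate number, NC1 or NC2 alone, only the compared libraries, Mock added to the reference, all other guides of the set as reference, and leaving out NC replicates and guides in turn. For the single-set labels, the suffix in set 2 was also added as a term. A minimum of 100 CPM, a robust fit, leaving out libraries under 50000 counts and, for Mock, 7 other labels as reference were added after seeing the data. The software was R 4.3.3 with data.table version 1.17.8, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Permutation tests used 100000 resamples and were two-sided.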

Results

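The measurements are 3'-end RNA read counts per gene from cells in which a dead Cas9 repressor was directed by transfected guide RNAs, with 360 capture and 360 no-capture libraries. The no-capture tables held 0 counts in every gene of every library, so all values below come from capture libraries. Their gene counts had set medians of 213652, 270698, 396494, 347339, 300314 and 291171 from set 1 to set 6. The smallest library held 807 gene counts and the largest 1007209. In all, 21211 genes had a count, with a median of 2873 genes per library.

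A few genes took most of the captured reads. H1-2, a linker histone gene, held 24.4% of all gene counts, and EIF3G, a subunit of a translation initiation factor, held 12.8%. The long non-coding RNA LINC02381 held 5.06%, the glycolytic enzyme gene ENO1 3.74%, the AP-1 transcription factor genes JUNB and JUN 3.07% and 2.55%, the divergent transcript ILF3-DT 2.31% and the nuclear RNA MALAT1 2.14%. The top 10 genes held 60.4% and 69 genes held 90% of the counts. Of the top 50 genes, 32 were annotated with a single exon, against 21.03% of all genes with a count. Among protein-coding genes the figures were 10 of 20 in the top 50 and 2.86%. Transcripts abundant in most cells were low, with 24.0 CPM for the actin gene ACTB, 22.6 CPM for the elongation factor gene EEF1A1 and 106 CPM for the glycolytic gene GAPDH.

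The first question was whether guides lowered the gene their label names. JUN was lower in the JUN guides, at 6879 CPM ± 3588 (SD, n = 10) against 20469 ± 1378 in NC (SD, n = 4), a log2 fold of -1.58 (SE 0.38). The label ZNF6 matched 89 symbols by its first letters, 8 of which were tested, and of these the antisense RNA ZNF674-AS1 was lower in the ZNF6 guides, at 1852 CPM ± 872 (SD, n = 10) against 3812 ± 443 (SD, n = 4), a log2 fold of -1.04 (SE 0.25). MALAT1 was lower in its own guides, at 10065 CPM ± 6145 (SD, n = 10) against 25497 ± 11704 (SD, n = 4), a log2 fold of -1.34 (SE 0.42). All 10 JUN guides lay below every NC library of their set, as did 9 of the 10 ZNF6 guides and 4 of the 10 MALAT1 guides. Of the 44 guide libraries of other labels in each set, 8, 2 and 4 did so for JUN, ZNF674-AS1 and MALAT1. JUN lies at 58780788 to 58784327 on chromosome 1, ZNF674-AS1 at 46545493 to 46548408 on chromosome X, and MALAT1 at 65497688 to 65506516 on chromosome 11 of hg38.

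Of the 21 pairs of label and gene tested, from 12 labels, these 3 were lower and 0 were higher in the edgeR test adjusted over the list alone (adjusted p = 8.55e-04 for JUN and for ZNF674-AS1, 0.0162 for MALAT1). Adjusted over all genes of the set, the p was 0.0612, 0.0641 and 0.360. NEAT1, the core RNA of paraspeckles, had 170 CPM in its own guides and 641 CPM in NC, a log2 fold of -1.64 (SE 0.63, n = 12 and 24) that did not pass (adjusted p = 0.0536). SOX2, a transcription factor of pluripotent and neural cells, had a log2 fold of -1.97 (SE 0.87) and DNAJC3-DT one of -1.76 (SE 0.81), also short of the threshold (adjusted p = 0.0945 and 0.0978). The other 15 pairs lay between -1.75 and 4.45 on the log2 scale, and those above 3 rest on NC groups with at most 1 count. DPH1, a diphthamide synthesis gene, and 4 further labels with a matched gene had too few counts to test. Of these, CTC was matched by its first letters only. Another 9 labels, named after clones, matched no current or GENCODE v29 name, so whether their target was measured is not known. With DESeq2 size factors in edgeR, ZNF674-AS1 alone stayed lower, the JUN fold was -0.82 (adjusted p = 0.0799) and the MALAT1 fold -0.54 (adjusted p = 0.251). MALAT1 also lost its call in DESeq2 (adjusted p = 0.218), in a robust edgeR fit (0.0517), without NC replicate 3 (0.118) and without guide 2 (0.0536).

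**Figure D1:**
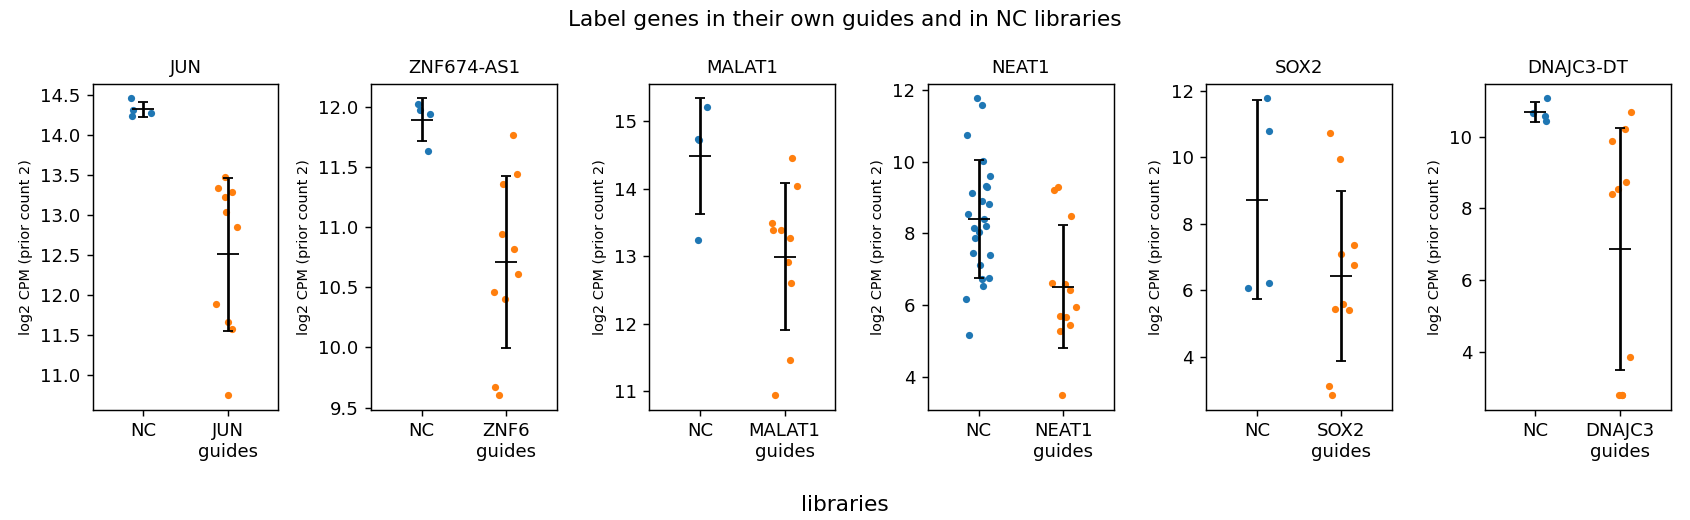
Log2 CPM (prior count 2) of 6 label genes in capture libraries of NC (blue) and of the label's own guides (orange); points are libraries, bars the mean and SD. The JUN guides all lie below the NC libraries, and 9 of the 10 ZNF6 guides lie below them for ZNF674-AS1.

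Mock differed from NC most of all labels present in every set, and 9 of its 36 lower calls were on the list of interferon response genes. The chemokine gene CCL5 had a mean of 2.03 CPM in Mock (n = 12) and 604 CPM in NC (n = 24), a log2 fold of -7.99 (SE 0.37). IFIT3, an antiviral protein gene, had 1 count in Mock against 944 in NC, a ratio of pooled values of 430 (95% interval 77.1 to 17016). No count in Mock was found for ISG15, a ubiquitin-like modifier, for the membrane antiviral gene IFITM3, or for IFI6, HERC5, IFIT2 and OAS3, a sensor of double-stranded RNA. These were at least 33.3-fold, 28.1-fold, 26.6-fold, 26.6-fold, 26.3-fold and 18.5-fold lower. STAT1, the transcription factor of interferon signalling, had a log2 fold of -3.70 (SE 0.82). All 5 of its Mock counts lie in 1 library of set 4, and without that library it was at least 19.9-fold lower (0 counts).

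All 9 measured genes of the interferon list were lower in Mock over all genes, and 9 adjusted over the list alone. Their median log2 fold was -5.99, and -4.73 with the genes at 0 counts placed at their bound. Each was lower in Mock in all 6 sets, with CCL5 between -7.29 and -5.73 log2 units by set. The list was called as lower by camera (adjusted p = 2.77e-32, and 1.04e-17 with an estimated correlation). The 9 genes together reached at most 15.4 CPM in a Mock library, and 346 of the 348 libraries of other labels lay above that. The exceptions, a SOX2 and a DNAJC3 library, had 0 CPM for the list. The smallest libraries of these labels held only 807 and 2942 gene counts, too few to show whether such genes are absent. The medians of the other 33 labels ran from 403 CPM in JUN guides to 1256 CPM in RP11_834 guides. The highest medians, of RP11_834, RP11_253, SOX21 and RP11_526, all belong to labels found only in set 1, so label and set cannot be told apart in this range.

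**Figure D2:**
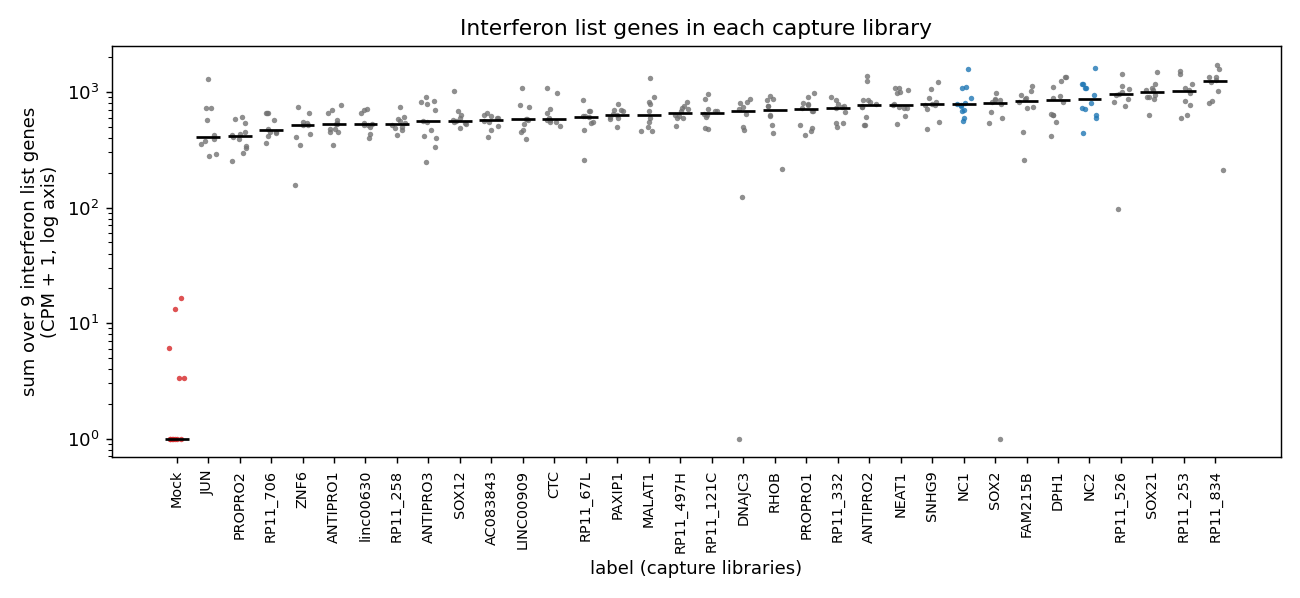
Sum of the 9 measured interferon list genes (CPM + 1, log axis) in each capture library by label, with Mock in red, NC1 and NC2 in blue and bars at the medians. No Mock library exceeds 15.4 CPM, and 346 of 348 other libraries lie higher.

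Other genes lower in Mock were B2M, the light chain of MHC class I (0 counts, at least 81.0-fold lower), and ENSG00000259563, a transcript of the same chromosome 15 region (0 counts, at least 23.6-fold lower; 10 of 24 NC libraries had a count). NFKBIA, the inhibitor of NF-kB, had a log2 fold of -2.83 (SE 0.78), from 7 counts in 2 Mock libraries. Without the Mock library of set 2 that holds 4 of them, it was 17.0-fold lower in pooled counts (95% interval 5.68 to 83.7), against 7.75-fold with it. JUNB had a log2 fold of -2.06 (SE 0.17, adjusted p = 5.54e-19), below the NC median in all 12 libraries. Genes outside the naming rule, picked after their values were seen, include further interferon-induced genes: IRF1 at -3.88 (SE 0.88, all 4 Mock counts in 1 library), HELZ2 at -3.49 (SE 0.31), the double-stranded RNA kinase EIF2AK2 at -2.29 (SE 0.46) and the RNA editing enzyme ADAR at -1.86 (SE 0.30).

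H1-2 was higher in Mock, at 436473 CPM against 215937 CPM, a log2 fold of 1.01 (SE 0.09), and so was ENO1, at 0.87 (SE 0.08, adjusted p = 2.61e-18). These CPM carry the TMM scaling and are not shares of the gene counts. Both lay above the NC median in all 12 Mock libraries. The tubulin gene TUBB was higher too, at 1.29 (SE 0.30), as were the actin gene ACTG1 at 1.05 (SE 0.31), LITAF, a lysosomal membrane protein gene, at 1.06 (SE 0.31) and the RNA SNHG29 at 2.19 (SE 0.63). Ribosomal protein genes as a list were higher (camera adjusted p = 2.29e-09, and 1.53e-04 with an estimated correlation). Of 41 measured, 4 rose over all genes (RPS4X at 0.90, RPS2 at 0.93, RPS6 at 0.96 and RPS3 at 1.10) and 12 adjusted over the list alone. RPS10, not on the list, was at 1.25 (SE 0.39). RPS3 was higher in 5 of 6 sets and the other named higher genes in 6 of 6.

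The hypoxia and glycolysis list was higher in Mock (adjusted p = 0.00128, and 0.00258 with an estimated correlation), with ENO1 as the 1 called gene of 5 and 2 adjusted over the list alone. The stress and unfolded protein response list passed with the preset correlation (adjusted p = 0.0423) and not with an estimated one (adjusted p = 0.0505). The same held for the diphthamide and elongation list (adjusted p = 0.0426, and 0.0509 with an estimated correlation). In both, 0 genes passed edgeR over all genes, with 0 and 2 adjusted over the list alone, and the elongation factor genes EEF2 and EEF1A1 had log2 folds of 0.89 and 1.22. Lists of G2/M (adjusted p = 0.409), S phase (0.790), paraspeckle (0.384) and mitochondrially encoded genes (0.837) were not called by camera.

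In all, 50 of 1140 genes differed between Mock and NC in edgeR, 14 higher and 36 lower, with 8 of the lower ones at 0 counts in Mock. DESeq2 called 84, 28 higher and 56 lower, of which 48 were shared, and NC2 alone as reference gave 33. A difference of the Mock effect between sets was found by edgeR for 0 of the 16 named genes with a count in Mock (0 at an unadjusted p under 0.05; not run in DESeq2). The other 8 had 0 counts in every Mock library and could not show one.

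**Figure D3:**
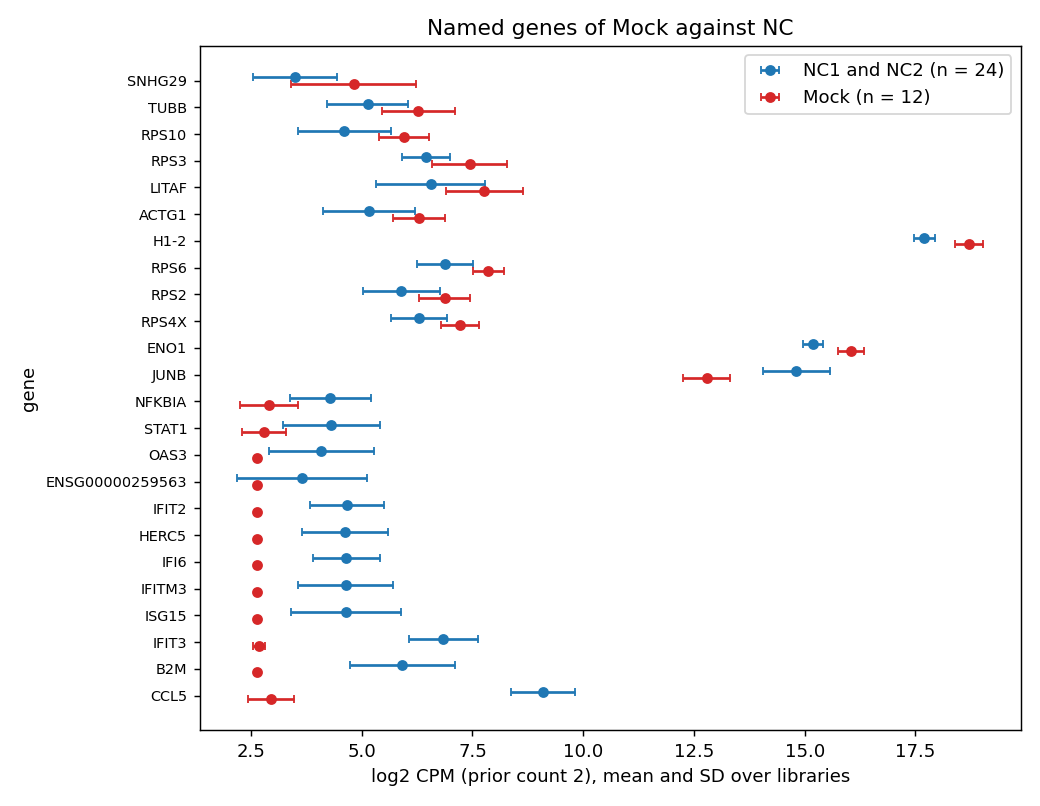
Mean and SD of log2 CPM (prior count 2) of the 24 named genes in Mock (red, n = 12) and NC (blue, n = 24) capture libraries. CCL5 shows the largest gap, and 8 genes with 0 counts in Mock sit at the value that the prior count gives.

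PROPRO2 shared 4 calls with Mock, with smaller log2 folds for JUNB, CCL5 and ENO1 and a larger one for RPS2 (the difference between both labels was not tested). JUNB was lower at -1.33 (SE 0.17, adjusted p = 7.96e-10), CCL5 at -1.40 (SE 0.24, adjusted p = 1.86e-05) and the cell adhesion gene NECTIN4 at -3.48 (SE 0.90, from 8 counts in 2 of 12 PROPRO2 libraries). ENO1 at 0.66 (SE 0.08, adjusted p = 4.82e-11), RPS2 at 1.16 (SE 0.25) and the non-coding RNA ENSG00000268205 at 0.76 (SE 0.17) were higher. JUNB and CCL5 lay below the NC median in all 12 libraries and ENO1 above it in all 12. These 6 genes were the calls over all genes, and DESeq2 gave 18, 4 higher and 14 lower. With DESeq2 size factors in edgeR the count was 10, 3 higher and 7 lower, with all 6 shared, and the median of all genes moved by -0.14 on the log2 scale. NC1 alone as reference gave 10 calls and NC2 alone 3.

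ANTIPRO1 and ANTIPRO3 moved the same abundant genes. JUNB was lower at -1.04 (SE 0.16, adjusted p = 5.37e-06) in ANTIPRO1 and at -1.23 (SE 0.17, adjusted p = 2.68e-08) in ANTIPRO3. ENO1 was higher at 0.44 (SE 0.08, adjusted p = 4.54e-05) and 0.47 (SE 0.08, adjusted p = 7.09e-06). The third call was CCL5 at -1.07 (SE 0.24, adjusted p = 0.00547) in ANTIPRO1, and C2orf49-DT, a divergent transcript, at -0.81 (SE 0.20, adjusted p = 0.0386) in ANTIPRO3. JUNB lay below the NC median in all 12 libraries of both labels, and ENO1 above it. Each label had 3 calls in edgeR, while DESeq2 gave 15 and 10. CCL5 in ANTIPRO3 did not pass in edgeR, at -0.90 (SE 0.23, adjusted p = 0.0550), and passed in DESeq2 (adjusted p = 3.24e-05). Against NC2 alone CCL5 in ANTIPRO1 lost its call (adjusted p = 0.0837).

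In PROPRO1 the histone gene H1-2 was higher at 0.44 (SE 0.09, adjusted p = 0.00555), above the NC median in all 12 libraries. The Wnt receptor gene FZD1 was called at 6.75 (SE 1.33), but 5 of 12 PROPRO1 and 2 of 24 NC libraries had a count. The divergent transcript EIF3J-DT was called at 4.08 (SE 1.0), above the NC median in 7 of 12 libraries. These were all 3 calls, DESeq2 gave 2 with 1 shared, and 0 remained with NC2 alone (51 genes had an unadjusted p under 0.05 in edgeR with both). In NEAT1 guides JUNB was lower at -0.64 (SE 0.16) and ILF3-DT at -0.59 (SE 0.14), and the RNA-binding protein gene HNRNPD was higher at 1.39 (SE 0.34), each with an adjusted p of 0.0484. Of these 3 calls 0 were left in a robust fit, without the set term, against NC2 alone, with DESeq2 size factors in edgeR, with only the compared libraries and with genes of at least 100 CPM. DESeq2 gave 1, NC1 alone 1, and leaving out NC replicates in turn 0 to 1, and the replicate block kept all 3.

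DPH1 and ANTIPRO2 had 0 genes called in edgeR (48 and 36 at an unadjusted p under 0.05), and DESeq2 called 0 and 1. NC1 and NC2 differed in 0 genes in both tools (40 at an unadjusted p under 0.05 in edgeR). JUNB was at -0.56 (SE 0.16, adjusted p = 0.301) in DPH1 and at -0.11 (SE 0.16, adjusted p = 0.999) in ANTIPRO2. DESeq2 size factors moved the median of all genes by -0.13 on the log2 scale in ANTIPRO2 and by less than 0.1 in the labels not named here with a shift.

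**Figure D4:**
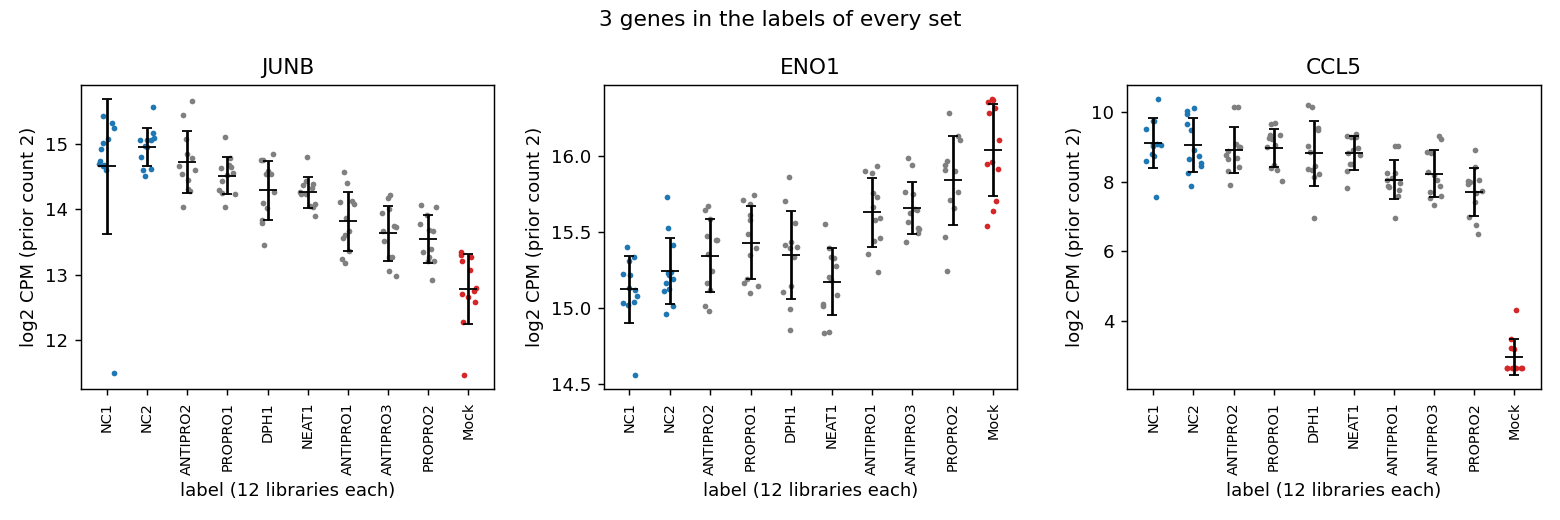
Log2 CPM (prior count 2) of JUNB, ENO1 and CCL5 in the 12 capture libraries of each label present in every set; points are libraries, bars the mean and SD, NC in blue and Mock in red. JUNB is lower than in NC for NEAT1, ANTIPRO1, ANTIPRO3, PROPRO2 and Mock, and 1 NC1 library lies far below the other NC libraries.

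Direct contrasts between labels, 4 chosen after these values were seen, gave JUNB at -0.96 (SE 0.18, adjusted p = 8.02e-04) in PROPRO2 against PROPRO1. CCL5 was lower there at -1.23 (SE 0.26, adjusted p = 0.00425), and ENO1 higher at 0.41 (SE 0.09, adjusted p = 0.00634), which DESeq2 did not call (adjusted p = 0.125). Against ANTIPRO2, JUNB was lower in ANTIPRO1 at -0.93 (SE 0.18, adjusted p = 0.00158) and in ANTIPRO3 at -1.12 (SE 0.18, adjusted p = 1.66e-05), the 1 call of each contrast in edgeR. DESeq2 called 3 genes in the former, also ENO1 (adjusted p = 0.0145) and CCL5 (adjusted p = 0.0250), and 2 in the latter, also ENO1 (adjusted p = 0.00619). ANTIPRO3 against ANTIPRO1 gave 0 calls in edgeR and in DESeq2 (29 at an unadjusted p under 0.05 in edgeR).

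Among gene lists, those of ribosomal proteins (higher), mitochondrially encoded genes (lower), hypoxia and glycolysis (higher) and interferon response (lower) were called by camera in PROPRO1, PROPRO2, ANTIPRO1 and ANTIPRO3. All of these comparisons use the same NC libraries, so their calls are not independent. With an estimated correlation the interferon call was kept in PROPRO1 (adjusted p = 0.0244) and PROPRO2 (adjusted p = 0.00867) and lost in ANTIPRO1 (adjusted p = 0.0799) and ANTIPRO3 (adjusted p = 0.0696), and the mitochondrial call was lost in PROPRO1 (adjusted p = 0.0607). Ribosomal protein medians were 0.19, 0.42, 0.33 and 0.37 on the log2 scale, and mitochondrial ones -0.29, -0.32, -0.30 and -0.35. For ribosomal proteins edgeR called 0 to 1 of 41 genes over all genes and 0 to 2 adjusted over the list alone, and for mitochondrial genes 0 of 12 on both counts. Of the hypoxia and glycolysis list, ENO1 was the 1 gene called over all genes in PROPRO2, ANTIPRO1 and ANTIPRO3 (0 in PROPRO1), with 1, 2, 1 and 3 genes adjusted over the list alone. The interferon list had medians of -0.57, -0.37, 0.019 and -0.21, with 0, 1, 1 and 2 genes adjusted over the list alone. In ANTIPRO1 its median had the other sign than the test, and it was -0.034 with DESeq2 size factors.

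The diphthamide and elongation list was higher in ANTIPRO1 and ANTIPRO3 by both forms of the test. The S phase list was lower in PROPRO1 (adjusted p = 0.0372, and 0.0505 with an estimated correlation) and ribosomal proteins were higher in DPH1 (adjusted p = 0.0212, and 0.117 with an estimated correlation), each with 0 genes called by edgeR. NEAT1 and ANTIPRO2 had 0 list calls by either form of camera. In all, 25 list calls were made, 15 higher and 10 lower, and 18 held with an estimated correlation. The calls not named with a p as lost were kept. The differences between labels in these lists were not tested.

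For the 24 labels of a single set, 57128 tests gave 11 calls in 4 genes, 3 higher and 8 lower. ENSG00000261094, a transcript on chromosome 9, was higher in RP11_121C, RP11_497H and RP11_332 guides at 2.07, 2.07 and 2.02 (SE 0.40 each), with means of 2975, 2973 and 2858 CPM against 707 CPM in the 4 NC libraries of set 3. The other 46 libraries of that set had a mean close to the guides, at 2324 to 2349 CPM. ENSG00000269973 was called as lower in RHOB, MALAT1, SOX2 and SOX12 guides, and the transcription factor gene GLIS2 in PAXIP1, RP11_258 and ZNF6 guides. Both rest on a single NC library, which held all 416 and all 177 of their NC counts. ENSG00000230551 was lower in SOX12 guides at -3.97 (SE 0.81), with 23.2 CPM against 396 CPM in NC and 64.6 CPM in the other 46 libraries of its set, so most of the gap lies in the 4 NC libraries. Unadjusted, 4808 tests had a p under 0.05 in edgeR, and DESeq2 gave 13 calls, all higher, of which 3 were shared. With DESeq2 size factors in edgeR there were 15 calls, 8 higher and 7 lower.

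Between the 24 NC libraries, the 83 genes of at least 1000 CPM had a median SD of 0.95 log2 units after removal of set means, and set medians ran from 0.32 to 1.25. The common dispersion was 0.794 over the 120 libraries of the labels of every set and 1.22 to 1.88 within sets.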

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

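Tests chosen only after the result was seen are the comparison of Mock with 7 other labels, that of JUNB with NC1 or NC2 alone, that of JUNB among the 7 labels, the correlations within sets and without the NC1 pair, both tests on the no-capture libraries, and the depth values that decide the thinning test. The others were chosen before their result was seen.

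The interferon list genes were lower in Mock than in NC, all 9 measured. Lower depth of the Mock libraries is not supported as the cause, although the bound written for it beforehand (at most 2 of 9 genes still lower after thinning every library to 66292 counts) was met, with 2. That bound was a poor criterion, because only 2 list genes still had enough counts to be tested and both were lower, and the verdict was changed after this was seen. What speaks against depth is that Mock libraries had more gene counts than NC (median 419138 against 324752) and that after thinning the highest Mock library had 2 list counts and the lowest NC library 31. Without the 20 genes with most counts the list median was -5.98. With 6 of the 9 genes at 0 counts in Mock this could hardly come out otherwise, so it does not decide whether a few genes taking most counts play a part. A property of the NC guides alone is excluded as the whole cause by all 9 genes also being lower than in 7 other labels. A response to guide delivery may underlie the pattern, a hypothesis found and tested on the same data. Other differences in how Mock wells were treated stay open and untested.

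JUNB was lower than NC in 5 of 8 labels present in every set. All these comparisons share the same NC libraries, and the median correlation of folds between labels without Mock was 0.414, against 0.332 in simulations of unchanged groups, so sharing gives most of that agreement over all genes. For JUNB it is opposed as the whole cause, since the 7 labels without NC and Mock differed among themselves (adjusted p = 4.18e-08, 1 of 7 genes called), in a comparison that uses no NC library as reference, and JUNB in Mock was also below these 7 labels (log2 fold -1.37, SE 0.19). In 50 simulations of unchanged groups the highest number of comparisons calling the same gene was 3. NEAT1 was not set against single other labels, so for NEAT1 the shared reference stays open. An offset of a single NC guide is opposed by 4 of the 5 comparisons calling JUNB against NC1 alone and 4 against NC2 alone.

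Whether JUNB follows the interferon response of a library was left undecided. Differences of CCL5 and JUNB between the 2 libraries of a label and set correlated (54 pairs without Mock, Pearson r = 0.57), but they are not independent, since JUNB differences had the same sign in 8 of 9 labels in set 4 and in set 6. With set means removed and values permuted within sets, r was 0.55 (p = 0.00224, adjusted 0.00672 over 3 relations tested), the rank correlation 0.30 (p = 0.0393, adjusted 0.118), and r without the NC1 pair of set 6 was 0.30 (p = 0.0394, adjusted 0.118). By set, r ran from -0.032 to 0.86 (9 pairs each). In the same test CCL5 with ENO1 (r = 0.16, adjusted p = 0.337) and JUNB with ENO1 (r = 0.28, adjusted p = 0.197) did not pass. Effects of the guides on JUNB itself, and technical variation that moves both genes in a library, stay open.

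No gene count was found in the no-capture libraries. Too few reads are opposed by a median of 738440 reads without a feature per no-capture library (22 to 2448077), above the 306094 gene counts of a median capture library, so this is a signal in data that the comparisons do not use. Counting on the opposite strand alone is opposed by 0 of 360 no-capture libraries with an ambiguous read (a read that overlaps several genes), while all 360 capture libraries had some (median 27653). Counted on the other strand, reads would still fall on genes there, and 21 of the 50 genes with most capture counts have an annotated gene opposite. Chromosome names or an annotation that did not match in counting, or another fault of the tables, stay open, and no biological explanation was tested.

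Of 44 groups of 10 libraries examined for a library far from the rest, 7 had one. The rule gives about 5 in 100 by chance for normally spread values. Gene counts were not put on a log scale, and LINC00630 and ZNF652 had a median of 0 CPM in their own guides. The 7 can therefore not be set against that rate. The lowest DNAJC3 library had 2942 gene counts (group median 263044) and the lowest SOX12 library 14312 (249878). The highest FAM215B library had 423604 (225363) and the highest ZNF6 library 420174 (298365). For label genes, the highest LINC00630 value in linc00630 guides was 7.64 log2 CPM (median 2.79), the lowest ZNF407-AS1 value in LINC00909 guides 2.96 (9.41) and the highest ZNF652 value in ZNF6 guides 5.05 (2.55).

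Other groupings of the same libraries within sets were drawn, 100 for each result with the real one included. The groupings kept the gene filter and dispersion trend of the real one, and no adjustment over these results was made. Chance can be excluded for Mock (50 genes, highest other 3) and PROPRO2 (6, highest other 3) in the main fit, with 1 grouping as large each. The same held for NEAT1, PROPRO1, ANTIPRO1 and ANTIPRO3 (3 each, highest other 2), and the label genes (3, highest other 2), but by a narrow margin. Against NC2 alone NEAT1 and PROPRO1 had 0 calls, and with DESeq2 size factors 1 label gene was lower, so chance stays open for these. In ANTIPRO1 and ANTIPRO3 JUNB stayed called against either NC guide alone. For the gene lists no other grouping had as many calls (24 with the dispersion used in these groupings, highest other 8). Each label was regrouped with NC separately, so the NC libraries shared by the real comparisons were not kept, and chance is not excluded for the lists together. Nor is it for some single lists, where several other groupings had a smaller camera p. The stress list in Mock had 0.00876, against 1.96e-06 in another grouping. The interferon list had 0.0163 in ANTIPRO3 and 0.0222 in ANTIPRO1, against 1.99e-04 and 9.93e-05. Between regrouped NC1 and NC2 libraries the stress list reached 2.99e-07. For the interferon list in Mock the camera p was 1.37e-29, against 1.13e-13 as the lowest other. Chance cannot be excluded for the 24 labels of a single set (11 calls, reached by 5 of 100, highest other 15). DPH1, ANTIPRO2 and NC1 against NC2 had 0 genes, which each of the 100 groupings reaches whatever the data (highest other 1), so for them this says nothing.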

How the results depend on the processing

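Alternatives chosen only after seeing the data are all those for capture libraries other than the planned ones for label genes and the estimated correlation of gene lists, since the plans named no-capture libraries; a minimum of 100 CPM, a robust fit, the removal of libraries under 50000 counts and 7 other labels as reference had not been planned for either kind. No alternative planned for no-capture libraries, nor the thinning of capture counts to their totals, could be run, as they held 0 counts. Of values for the summary results, 91 stayed on the same side of the threshold or within 1.5 times, 40 moved further, 17 gained and 10 lost a call. For single label genes and named genes, 854 kept direction and side, 127 lost and 16 gained a call, and 30 reversed, none of them called. JUNB, CCL5 and ENO1 kept their direction in Mock against NC1 alone, NC2 alone, 7 other labels and in DESeq2, with folds of -2.14 to -1.37, -8.27 to -7.44 and 0.55 to 0.93. Depth limits what can be seen: 1140 of 21211 genes passed the filter for the labels of every set. The cause of a changed count was not tested unless given.

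With DESeq2, calls were 84 in Mock, 1 in NEAT1, 18 in PROPRO2, 15 in ANTIPRO1, 1 in ANTIPRO2 and 10 in ANTIPRO3. With DESeq2 size factors in edgeR they were 0 in NEAT1 and 10 in PROPRO2, and 1 label gene was lower. Without a filter on low counts they were 554 in Mock, 398 in NEAT1, 323 in DPH1, 3.3e+02 (rounded) in PROPRO1, 430 in PROPRO2, 387 in ANTIPRO1, 347 in ANTIPRO2, 458 in ANTIPRO3, 114 in the single-set labels and 275 between NC1 and NC2, which compares 12 libraries with 12 rather than with 24. With genes of at least 100 CPM, where fewer genes are tested, they were 0 in NEAT1, 5 in DPH1, 5 in PROPRO1, 12 in ANTIPRO1, 2 in ANTIPRO2, 8 in ANTIPRO3 and 1 between NC1 and NC2.

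Against NC2 only, calls were 33 in Mock, 0 in NEAT1, 0 in PROPRO1 and 3 in PROPRO2, and against NC1 only 1 in NEAT1, 1 in PROPRO1, 10 in PROPRO2 and 1 in ANTIPRO2. With only the libraries compared, which are fewer, they were 31 in Mock, 0 in NEAT1 and 1 in PROPRO1. NEAT1 had 0 without the set term and 0 in a robust fit, where the single-set labels had 21. For these labels, adding Mock to the reference gave 33 calls (15 higher, 18 lower), all other guides of the set gave 49 (39 higher, 10 lower), and those with at least 100 CPM gave 28. Lower label genes were 6 against all other guides.

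The replicate numbers do not pair the libraries over well-counted genes: of 270 pairs of labels within sets, 104 had a correlation of deviations over 0.1 over 83 genes, and set medians were -0.032 to 0.13. JUNB had replicate differences of the same sign in 8 of 9 labels in set 4 and in set 6. With set and replicate number as a block, Mock had 53 calls, ANTIPRO2 1 and ANTIPRO3 5, and the block moved no other count of calls by over 1.5 times.

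Leaving out NC replicates 1 to 4 in turn, each of which removes 1 NC library per set, gave 0 to 1 calls in NEAT1 (0 without replicate 1, 1 without replicate 3), 0 to 2 in DPH1 (2 without replicate 2), 4 to 5 in ANTIPRO1 (5 without replicate 3), 1 to 2 in ANTIPRO2 and 2 to 5 in ANTIPRO3 (5 without replicate 2). The single-set labels had 4 to 17 (4 without replicate 2, 17 without replicate 4). Lower label genes were 2 to 5 over NC replicates and guides left out in turn (5 without NC replicate 1, guide 7 or guide 8, and 2 without guide 2).

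Reversed log2 folds, all uncalled before and after, were small or from genes of few counts. AC083843.2 was at 0.019 with DESeq2 and with its size factors, at 0.069 with Mock in the reference and between -0.22 and 0.14 with libraries left out. LINC00630 was at -2.31 with Mock in the reference and -0.021 against all other guides. PAXIP1-DT was at 0.22 and 0.042 in these, and between -0.10 and 0.083 with libraries left out. Against all other guides ZNF407-AS1 was at -0.031, ZNF669 at -0.14, ZNF655 at -0.29 and ZNF652 at -0.65. With libraries left out, PAXIP1 ran from -0.017 to 0.88, SOX21-AS1 from -1.78 to 0.97, ZNF669 from -0.34 to 0.76, ZNF655 from -0.045 to 0.97, ZNF638 from -1.24 to 0.41 and ZNF621 from -2.22 to 3.04.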

Other observations

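The comparison of each single-set label with all other guides of its set, restricted to genes of at least 100 CPM, was chosen after seeing the data. It gave 28 calls among 4264 tests in edgeR, 15 higher and 13 lower. Some higher calls rest on a few libraries with extreme values: AC087481.3 in MALAT1 guides at 5.35 (SE 0.86) had a median of 20.5 CPM against 177 CPM in the other guides, and FGD5-AS1 in RP11_706 guides at 2.95 (SE 0.42) had 64.2 CPM against 57.8 CPM. The genes named next were picked after their values were seen and are all lower. ENSG00000239407 was lower in linc00630 guides at -1.52 (SE 0.24, adjusted p = 3.13e-05), below all 48 other guide libraries in 8 of 10 libraries. This transcript lies on chromosome X at 102884414 to 102906158 (hg38), and its start overlaps the end of LINC00630 at 102885406 on the same strand. LINC02381 was lower in RP11_834 guides at -1.51 (SE 0.26, adjusted p = 2.37e-04), below all other guides in 6 of 10 libraries, and ENSG00000268205 was lower in CTC guides at -1.23 (SE 0.22, adjusted p = 2.37e-04) and in MALAT1 guides at -1.0 (SE 0.24, adjusted p = 0.0218). Whether LINC02381 and ENSG00000268205 are the genes that the labels RP11_834 and CTC name could not be told from the gene names used. MCPH1-DT was lower in JUN guides at -1.49 (SE 0.28, adjusted p = 7.17e-04), and the glycolytic gene ENO1 in RP11_706 guides at -0.56 (SE 0.14, adjusted p = 0.0489).

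With the same reference and all genes, 6 label genes were lower, adjusted over their list alone, of which ZNF674-AS1 and JUN also passed over all genes (adjusted p = 4.28e-09 and 7.97e-07). RHOB (0.128), MALAT1 (0.0896), NEAT1 (0.796) and SOX2 (0.552) did not. ZNF674-AS1 was at -1.61 (SE 0.19), JUN at -1.90 (SE 0.26), the small GTPase gene RHOB at -5.84 (SE 1.52, from 14 counts in its 10 guides), MALAT1 at -1.01 (SE 0.28), NEAT1 at -1.79 (SE 0.58) and SOX2 at -1.59 (SE 0.60). For RHOB the medians differ far less than this fold, with 1.93 CPM in its guides and 8.51 CPM in 44 guide libraries of other labels. Against NC its log2 fold was -0.94 (SE 1.52, edgeR adjusted p = 0.808 over the list).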
